A study of Homo sapiens with 12 samples.

How the data were processed

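RNA of H9 human embryonic stem cells and of their progeny on 11 later days of neuronal differentiation was sequenced in 12 libraries, 1 per day from day 0 to day 22, with TruSeq RNA libraries made from 1 ug of total RNA. Whether the days come from separate cultures is not stated. According to the authors' processing notes, reads were handled with TopHat2 2.0.4 and Cufflinks 2.0.2 on hg19. The deposited table gives log2 values, which the authors do not describe further. They were read here as the binary logarithm of FPKM plus 1, since none lies below 0, exact zeros are present, and the back-transformed columns sum to amounts usual for FPKM. The annotation, the rule by which rows were kept and any scaling between libraries are not stated. Read depth is not given in the sources used here, so the precision of a single value is unknown and low values may rest on few reads.

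Gene rows with at least 1 FPKM in at least 2 libraries (13701) were tested on the log2 values as deposited. A cubic polynomial of day was fitted to each row with limma 3.58.1 in R 4.3.3, with moderated variances and a trend of variance with mean, leaving 8 residual degrees of freedom. The moderated F test asks whether a gene varied with day, and the 2-sided test of the linear term whether it rose or fell. The size given for a gene is the change of the linear term over the 22 days with its standard error. P-values were adjusted by the Benjamini-Hochberg method over all tested rows, and for list members also over the list alone, with a threshold of 0.05. A transient peak or trough is a gene past the F test whose fitted extreme lies between days 4 and 18, at least 1 log2 unit beyond both fitted ends. On simulated data with 200 changed genes, 18% of trends of 1 log2 unit and 78% of trends of 2 were recovered, with 4% false calls. Many more genes (5544) varied in the real data, so these rates need not carry over.

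Gene lists were written before the data were examined, as were the fit, the filter, the thresholds, the alternatives not marked otherwise and the rule for naming genes. Lists with at least 5 tested members were tested with fry on the linear term, and against all other genes with camera, once with a preset correlation of 0.01 and once with the correlation estimated from the residuals. Pairs of days were described by the median difference of a list and its percentile among 10000 random lists drawn from 20 bins of expression. Steps between neighbouring days were counted at 1 log2 unit. Contiguous segments (2 to 6) minimized the sum of squares within segments, with 1000 bootstraps of genes, and libraries were compared by principal components and Spearman correlation, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

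Genes were named by rule: 42 landmark genes; up to 4 members of each list with the largest fitted range among those past the F test; the 10 rises and 10 falls with the largest fitted difference between the ends; the 10 highest peaks and 5 deepest troughs; and the 3 largest differences each way per step. ALB, DLX2, DLX6-AS1, FN1, GATA4, LHX5, MT1G, MT2A, POU3F3, PTBP1, REST, SLC18A2, ZEB1 and the genes named by family in the closing section were chosen after their values were seen, as were the genes named for a step outside the rule. Transcript lengths came from an annotation of another build than hg19 and were matched by symbol. Near-identical copies cannot be separated in these values: pseudogenes of POU5F1, NANOG and TDGF1, LEFTY1 and its neighbour, metallothioneins, actins, histones and ribosomal proteins. Strand was not recorded, so DLX6-AS1 may include reads of DLX6.

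Alternatives were 2 smaller pseudocounts (0.1 and 0.01), no filter, a filter of 5 FPKM, upper-quartile scaling, quantile normalization, a quadratic curve, a straight line, a natural spline, moderation without a trend, unit variance for the segments, a step of 2 log2 units, days 2 to 22 only, and each day left out in turn. Added after seeing the data were an indicator for days 8, 10, 18 and 22, leaving out these days, leaving out small RNA rows, and removing each library's trend with transcript length. The labels name no other factor, and none of the libraries was left out of the analysis as reported.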

Results

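The series followed human embryonic stem cells of the established line H9 as they were differentiated toward neuronal cells, with the stages that determine this commitment as its stated subject. RNA was sequenced in 12 libraries, 1 for every other day from day 0 to day 22, so no day has a replicate. The deposited table holds log2 values, taken here as log2(FPKM + 1), and 13701 of its gene rows reached 1 FPKM in at least 2 libraries and were tested. Read depth is not given in the sources used here, so no counting error can be attached to a single value. The row of the microRNA gene MIR663A alone held 182774 and 218952 FPKM on days 18 and 20; it held 112064, 92478 and 71830.2 FPKM on days 2, 4 and 6 and is listed at 0 on the 7 other days.

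The libraries of days 8, 10, 18 and 22 stood apart in their content of short transcripts. Genes for ribosomal proteins made up 25.6, 24.8, 21.9 and 19.1% of the FPKM sum without small RNA rows on these days, against 6.1 to 14.9% on the other 8. Of the whole sum, which includes MIR663A, they made up 25.4, 24.6, 12.1 and 18.9% on these days, and 14.8% on day 12. Across genes, the rank correlation of a library's deviation from each gene's mean with transcript length was -0.35, -0.35, -0.24 and -0.26, and lay between -0.02 and 0.29 elsewhere. Genes within a library are not independent replicates. The list of replication-dependent histone genes, whose mRNAs lack a poly(A) tail, lay above the median of all genes by 2.01, 1.73 and 1.2 log2 units on days 8, 10 and 18, and at -0.26 on day 22.

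**Figure D1:**
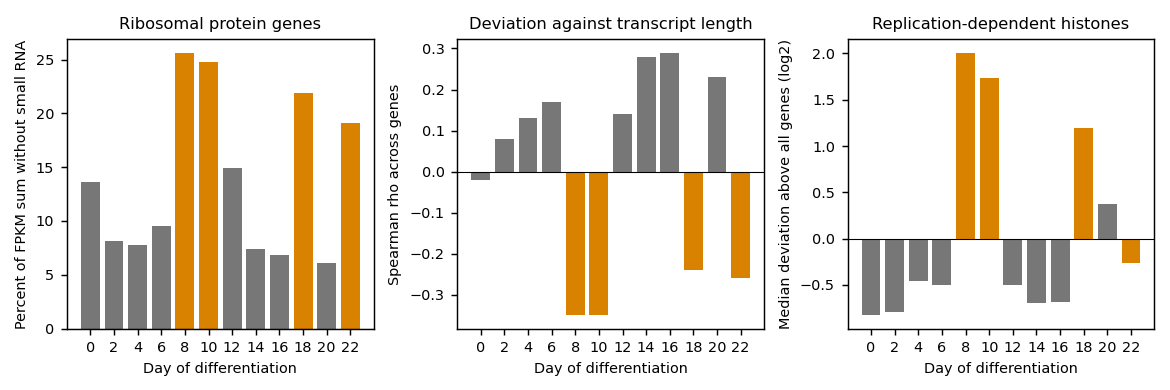
Share of the FPKM sum without small RNA rows held by ribosomal protein genes (percent), rank correlation across genes of each library's deviation with transcript length, and median deviation of 17 histone genes above all genes (log2 units), with 1 bar per library along the day of differentiation. Orange bars mark days 8, 10, 18 and 22, where the ribosomal protein share was 19.1% or more and the correlation -0.24 or lower.

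The first comparison asked which genes changed along the course. POU5F1, a core transcription factor of pluripotency, fell by 9.24 ± 0.61 log2 units over the 22 days (limma, adjusted p = 4.7e-06), from 595 FPKM on day 0 to 6.8 on day 14 and 7.07 on day 22. SOX1, an early marker of neuroectoderm, rose by 5.65 ± 0.33 (adjusted p = 2.5e-06), and DCX, a microtubule protein of young neurons, rose by 5.28 ± 0.69 (adjusted p = 0.00019). These sizes are the change along the straight-line part of a cubic curve of day, with the standard error of the fit to 12 libraries. SOX2, which both stem cells and neural progenitors use, varied with day (adjusted p = 0.013) without a linear trend (-0.70 ± 0.30, adjusted p = 0.082) and stayed between 95 and 332 FPKM; the trend was -0.08 after upper-quartile scaling and 0.28 after quantile normalization.

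Over all genes, 5544 of 13701 (40.5%) varied with day at an adjusted p under 0.05, 1755 rose and 4416 fell along the linear term. Of these, 915 rose and 3034 fell by at least 1 log2 unit between the fitted ends, against 1868 and 1330 after upper-quartile scaling. Falls made up 71.6% of the trends called in the values as deposited, 43.1% after upper-quartile scaling (3037 rose, 2304 fell) and 51.2% after quantile normalization (2354 rose, 2474 fell). The trend of the median gene was -0.41 log2 units as deposited and 0.11 after upper-quartile scaling, so a fall of about this size depends on the scaling. All 1755 rising genes and 2304 of the falling genes kept their call after upper-quartile scaling, and 32 called genes changed sign. With an indicator for the libraries of days 8, 10, 18 and 22, chosen after seeing the data, 8360 genes varied, 2290 rose and 5606 fell; 1695 of the 1755 rises and 4291 of the 4416 falls were called again. Each day is 1 library, so a p-value here measures scatter about a smooth curve of day with 8 residual degrees of freedom, not variation between cultures, and neighbouring libraries may not be independent.

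**Figure D2:**
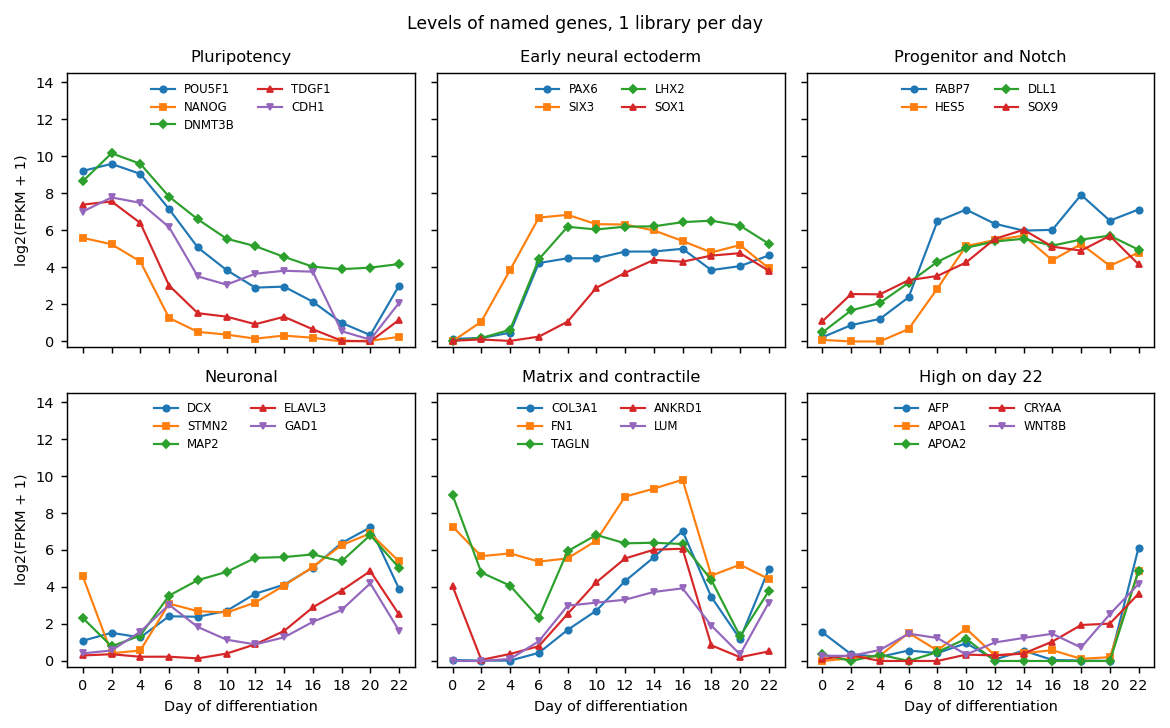
Expression of 28 genes as log2(FPKM + 1) against the day of differentiation, with 1 point per library and lines joining neighbouring days. POU5F1 goes from 595 FPKM on day 0 to 0.269 on day 20, LHX2 from 0.029 to 75.7, DCX from 1.14 to 148, and AFP stands at 68.7 FPKM on day 22.

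Pluripotency genes fell as a group. Of the 28 genes of this list, 27 fell (28 adjusted over the list alone) and none rose, with a median trend of -3.35 log2 units (fry, adjusted p = 3.7e-05; adjusted p = 0.34 with an estimated correlation). NANOG, a homeobox factor of pluripotent cells, was at 47.5, 37.2, 19 and 1.41 FPKM on days 0 to 6 and fell by 5.47 ± 0.54. The co-receptor gene TDGF1 fell by 7.46 ± 0.72 and PRDM14, a repressor of differentiation genes, fell by 8.11 ± 0.86, the latter after 179.7 FPKM on day 2. DNMT3B, a de novo DNA methyltransferase abundant in stem cells, went from 403 FPKM on day 0 to 1156 on day 2 and 17.2 on day 22 (trend -6.54 ± 0.51). LIN28A, an RNA-binding protein that blocks let-7 maturation, fell by 4.12 ± 0.41 and was still at 649 FPKM on day 6 and at 96.9 on day 16. POU5F1, TDGF1 and CDH1, the last a member of the epithelial list, were higher on day 22 than on day 20. They stood at 7.07, 1.24 and 3.24 FPKM against 0.269, 0 and 0.070. The pluripotency list as a whole had a median difference of 0.19 between these days (percentile 92.5 among random lists). Of its 28 members, 6 were higher and 0 lower by at least 1 log2 unit.

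Epithelial and surface ectoderm genes fell alongside: 16 of 17 measured members fell (16 adjusted over the list alone), with a median of -3.45 (fry, adjusted p = 0.0011; adjusted p = 0.48 with an estimated correlation). CDH1, the cadherin of epithelial junctions, fell by 7.02 ± 0.99, ESRP1, a splicing regulator of epithelia, fell by 6.28 ± 0.67, and EPCAM fell by 5.32 ± 0.71. The cadherin gene CDH2, a member of the list of neural progenitors and radial glia, was at 121 FPKM on day 0, 12.9 on day 4 and 212 on day 16. Its trend was 2.27 ± 0.75 (limma, adjusted p = 0.028). This call was lost without day 2, 4, 16 or 20 (trends of 1.53 to 2.23). ZEB1, a repressor of CDH1 chosen after its values were seen, rose by 5.09 ± 0.43 (adjusted p = 1.8e-05), from 0.255 FPKM on day 0 to 35.9 on day 20.

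Early neural ectoderm genes rose. Of 21 measured members, 13 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 3.02 (fry, adjusted p = 2.2e-05; adjusted p = 0.051 with an estimated correlation). PAX6, an eye and forebrain factor, went from 0.389 FPKM on day 4 to 17.9 on day 6 (trend 4.37 ± 0.73), and LHX2, a LIM homeobox factor of the same regions, from 0.552 to 20.7 and then 72.6 on day 8 (trend 6.3 ± 0.75). SIX3 was earlier, at 13.6 FPKM on day 4 and 114 on day 8; its trend of 3.02 ± 0.57 was 1.1 and not called without day 0, and 1.94 without day 2. DLK1, a secreted Notch-related protein, reached 1481 FPKM on day 14 (trend 7.66 ± 0.88). HESX1, a repressor of the anterior neural plate, fell by 3.34 ± 0.61, or by 5.11 without day 0, after 57.3 FPKM on day 6, and was at 2.03 on day 12. OTX2 varied with day (adjusted p = 0.032) without a linear trend and lay between 22.8 and 137 FPKM.

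Genes that pattern the forebrain rose. Of more caudal regions, 9 of 17 midbrain and hindbrain genes in the table were measurable, and none of 10 HOX genes. In the forebrain list 13 of 18 members rose and 2 fell (13 and 2 adjusted over the list alone; fry, adjusted p = 2.6e-06; adjusted p = 0.0059 with an estimated correlation). The cortical factor EMX2 rose by 6.32 ± 0.47, to 47.2 FPKM on day 22. Of 9 measured midbrain and hindbrain genes none rose and 1, IRX2, fell by 3.35 ± 0.62 (list adjusted p = 0.77; median 0.26, mean -0.04). The linear term does not describe a passing rise. The median deviation of the midbrain and hindbrain list was -0.49 on day 0, 0.66 on day 10 and -0.65 on day 20. From day 0 to day 6 its median difference was 0.45 (percentile 98.4 among random lists), with 3 of 9 members higher by at least 1 log2 unit. All 10 HOX genes of the HOX list that are in the table stayed below the expression filter, HOXB2 with a highest value of 1.41 FPKM on day 22 among them. The midbrain factor EN1 reached no more than 0.127 FPKM. In the eye field list 4 of 6 members rose and none fell (adjusted p = 0.06, not called; 0.014 without day 22 and 0.033 after upper-quartile scaling, with a range of 0.0012 to 0.13 over the alternatives). DCT, a pigment enzyme, rose by 3.28 ± 0.55.

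Progenitor and Notch genes rose as well. In the list of neural progenitors and radial glia 13 of 23 members rose and 2 fell (the same counts adjusted over the list alone; fry, adjusted p = 0.00011; adjusted p = 0.051 with an estimated correlation). FABP7, a lipid-binding protein of radial glia, went from 4.23 FPKM on day 6 to 88.8 on day 8 and rose by 7.3 ± 0.96. HES5, a Notch effector, went from 0.594 to 6.26 and 34.7 FPKM on days 6, 8 and 10 (trend 5.89 ± 0.81), and the glial and progenitor factor SOX9 rose by 3.72 ± 0.44. The intermediate filament gene NES varied with day (adjusted p = 0.005) without a linear trend (0.61 ± 0.27, adjusted p = 0.09; 1.22 and called after upper-quartile scaling and 1.32 and 0.92 and called without day 0 or day 22). Among Notch ligands and proneural factors 11 of 13 rose and none fell (11 adjusted over the list alone; fry, adjusted p = 1.6e-07; adjusted p = 0.0059 with an estimated correlation). The ligand gene DLL1 rose by 4.76 ± 0.29, from 0.401 FPKM on day 0 to 45.9 on day 14. NEUROG2, a proneural factor of cortex, had its highest value, 2.75 FPKM, on day 22, and its trend of 1.15 ± 0.28 was 0.71 and not called without that day.

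Neuronal genes rose late, up to day 20. In the list of neuronal cytoskeleton and identity 19 of 27 members rose and 2 fell (the same counts adjusted over the list alone; fry, adjusted p = 0.0025; adjusted p = 0.31 with an estimated correlation). DCX was at 16.4, 32.2, 81.9, 148 and 13.9 FPKM on days 14 to 22. MAP2, a dendritic microtubule protein, rose by 4.91 ± 0.64 with 111 FPKM on day 20, STMN2, a tubulin-binding protein of growth cones, rose by 4.68 ± 0.86, and the RNA-binding protein gene ELAVL3 rose by 4.16 ± 0.59. The call for TUBB3 (trend 1.64 ± 0.49, adjusted p = 0.019) was lost without day 6, 18 or 20 (trends of 1.11 to 1.37), and the trend was 2.68 without day 0. The median of this list was 1.71. The library of day 22 is also 1 of the 4 high in short transcripts.

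Genes of synapses, channels and transmitters were split. In the synapse list 10 of 27 members rose and 4 fell (11 and 4 adjusted over the list alone; fry, adjusted p = 0.18; 0.0012 without day 22, with a range of 0.0012 to 0.53 over the alternatives). SNAP25, a vesicle fusion protein, rose by 2.19 ± 0.41 to 6.22 FPKM on day 20, SYN3 fell by 2.99 ± 0.61, and the calcium sensor gene SYT1 was not called (0.39 ± 0.43). Among ion channels 4 of 13 rose, KCNQ3 by 1.94 ± 0.27 and KCNC1 by 2.8 ± 0.43, and 2 fell, CACNA2D1 among them (-2.64 ± 0.66; list adjusted p = 0.17, 0.00018 without day 22, with a range of 0.00018 to 0.42 over the alternatives). In the GABAergic list 7 of 14 rose and 2 fell (adjusted p = 0.088; 0.00018 without day 22 and 0.048 after upper-quartile scaling, with a range of 0.00018 to 0.29 over the alternatives). The ventral forebrain factor GSX2 rose by 4.08 ± 0.59. GAD1, which makes GABA, was at 17.3 FPKM on day 20 and 2.12 on day 22 and was not called (adjusted p = 0.093).

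In the glutamatergic list 4 of 11 rose and 1 fell (fry, adjusted p = 0.027; adjusted p = 0.43 with an estimated correlation; the list call was lost without day 2, 4 or 8, with adjusted p up to 0.094). The cortical factor TBR1 rose by 2.65 ± 0.33 and the AMPA receptor gene GRIA2 rose by 2.71 ± 0.70, or by 1.74 without day 20, when it stood at 14.9 FPKM. The vesicular transporter gene SLC17A6 stayed below the filter with at most 1.31 FPKM. Of 6 measured genes for other transmitters 1 rose and 2 fell. TH, which starts dopamine synthesis, rose by 1.07 ± 0.22 but stayed at or below 1.15 FPKM (list adjusted p = 0.18, 0.039 without day 22, with a range of 0.006 to 0.47 over the alternatives). The falling genes were SLC18A2, a vesicular transporter chosen after its values were seen, and GATA3 (trend -1.47 ± 0.52), whose call was lost without day 4, 6, 8, 18, 20 or 22 (trends of -1.04 to -1.52) and after upper-quartile scaling (-1.22). ISL1 was not called (1.28 ± 0.59, adjusted p = 0.099). Among splicing regulators 11 of 21 rose and 5 fell (adjusted p = 0.32; 1.7e-05 without day 22, with a range of 1.7e-05 to 0.56 over the alternatives). CELF3 rose by 3.81 ± 0.64, and PTBP1 and REST, repressors of neuronal exons and genes, chosen after their values were seen, had trends of -2.03 ± 0.31 and -1.77 ± 0.33, the former -1.08 after quantile normalization.

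Axon guidance genes went both ways, with 11 of 25 up and 6 down (12 and 6 adjusted over the list alone; fry, adjusted p = 0.28; 0.021 without day 22, with a range of 0.0064 to 0.5 over the alternatives). The netrin receptor gene DCC rose by 4.6 ± 0.61 and SLIT2, a repellent ligand, rose by 3.85 ± 0.81, while SEMA6A fell by 4.3 ± 0.29. WNT pathway genes rose in 9 of 19 and none fell (9 and 1 adjusted over the list alone; fry, adjusted p = 0.00071; adjusted p = 0.1 with an estimated correlation). WNT5B rose by 4.47 ± 0.80, and WNT8B reached 17 FPKM on day 22 (trend 2.48 ± 0.42, 1.5 without that day). In the hedgehog list 4 of 11 rose and 1 fell (6 and 1 adjusted over the list alone; fry, adjusted p = 0.024; 0.73 without day 0, with a range of 0.00075 to 0.73 over the alternatives; adjusted p = 0.48 with an estimated correlation). The co-receptor gene BOC rose by 3.87 ± 0.36, and GLI1, a transcriptional target of the pathway, fell by 2.87 ± 0.53.

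FGF genes fell in 7 of 20 cases and rose in 4 (7 and 5 adjusted over the list alone; fry, adjusted p = 0.032, 0.28 after upper-quartile scaling, with a range of 0.0087 to 0.54 over the alternatives; adjusted p = 0.99 with an estimated correlation). The receptor gene FGFR4 fell by 4.0 ± 0.24, FGF2, a supplement of stem cell media, fell by 3.04 ± 0.57, and SPRY4, a feedback inhibitor, fell by 2.6 ± 0.42. The FGF list lost its call also without day 0, 2, 4, 8, 20 or 22, and its median of -0.30 was 0.27 after upper-quartile scaling. Among BMP and TGF-beta genes 10 of 21 fell and 1 rose (adjusted p = 0.095, not called; 0.0087 without day 22, with a range of 0.0087 to 0.36 over the alternatives). The Nodal antagonist LEFTY1 was at 114 FPKM on day 0 and 3.12 on day 2 (trend -3.52 ± 0.55, -1.03 without day 0). In the retinoic acid list 3 of 14 fell and 2 rose; the test gave a fall (adjusted p = 0.021, 0.17 after upper-quartile scaling, with a range of 0.00018 to 0.17 over the alternatives; adjusted p = 0.82 with an estimated correlation) and the mean was -0.55, while the median was 0.12. CYP26A1, which degrades retinoic acid, fell by 5.57 ± 0.65 and the receptor gene RARG fell by 3.37 ± 0.32; the list call was also lost without day 18.

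No gene of the neural crest, mesoderm or trophoblast lists rose along the linear term. In the endoderm list 1 of 7 measured members rose and 3 fell. The test gave a fall (fry, adjusted p = 0.022, 0.12 without day 0, with a range of 0.00013 to 0.51 over the alternatives; not called without day 20 either; adjusted p = 0.99 with an estimated correlation) and the mean was -0.49, while the median was 1.64, or -1.0 without day 22. CER1, a secreted antagonist of anterior endoderm, stood at 211 FPKM on day 0 and 8.53 on day 2 (trend -4.87 ± 0.44, -2.44 without day 0). The plasma protein genes AFP, APOA1 and APOA2 were at 68.7, 27.9 and 28.6 FPKM on day 22, and AFP was at or below 1.93, APOA1 2.37 and APOA2 1.3 FPKM on all earlier days; none was called along the linear term. SOX17, GATA4, ALB and CDX2 stayed below the filter. Neural crest genes fell in 4 of 13 (fry, adjusted p = 0.033, 0.12 after upper-quartile scaling, with a range of 0.001 to 0.34 over the alternatives; adjusted p = 0.92 with an estimated correlation), and ERBB3 fell by 4.02 ± 0.45. The call for SOX10 (trend -0.75 ± 0.22) was lost without day 2 or 18 (-0.61 and -0.66) and after upper-quartile scaling (-0.46), and was -1.31 without day 22, and the neural crest list lost its call without day 2, 4, 8, 10, 12, 18 or 20.

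In the glia list 5 of 10 members fell and 2 rose (fry, adjusted p = 0.0011, 0.079 without day 0, with a range of 0.0004 to 0.14 over the alternatives; adjusted p = 0.99 with an estimated correlation), with a median of -0.34 that was 0.03 after upper-quartile scaling. GJA1, a gap junction protein, fell by 3.49 ± 0.60, OLIG2, a ventral progenitor factor, rose by 1.2 ± 0.28 to 1.56 FPKM on day 20, and GFAP stayed at or below 0.212 FPKM. Choroid plexus and roof plate genes rose in 5 of 10 (fry, adjusted p = 0.035; adjusted p = 0.48 with an estimated correlation), RSPO1, a WNT agonist, with a trend of 3.02 ± 0.41; the list call was lost without day 0, 2, 4, 8, 10, 12 or 14 (adjusted p up to 0.13). None of the 7 measured primitive streak and mesoderm genes rose and 2 fell (adjusted p = 0.19; 0.43 after upper-quartile scaling, with a range of 0.066 to 0.97 over the alternatives). KDR, a VEGF receptor, fell by 4.15 ± 0.63; in the blood and endothelium list, with 4 measured genes and no list test, it was the 1 gene that fell. In the trophoblast list 4 of 13 fell (3 adjusted over the list alone; adjusted p = 0.17; median 0.02, mean -0.47), TFAP2C, an AP-2 factor also found in stem cells, with a trend of -4.18 ± 0.41. GABRP, another member, was at 38.9 FPKM on day 16 and 1.74 on day 18.

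Proliferation genes fell moderately along the linear term. Between the libraries of days 0 and 22 alone, they did not fall beyond random lists of similar expression. There the mitosis and DNA replication lists had medians of -0.37 and -0.14 (percentiles 89.2 and 99.4), against -0.63 and -0.64 in random lists. In the mitosis list 14 of 23 members fell (16 adjusted over the list alone; fry, adjusted p = 0.00017; adjusted p = 0.48 with an estimated correlation), with a median of -1.03, or -0.43 after upper-quartile scaling. The checkpoint kinase gene BUB1 fell by 2.43 ± 0.48, and the mitotic kinase gene PLK1 fell by 2.08 ± 0.28, or by 1.34 after quantile normalization. MKI67 had a trend of -0.85 ± 0.27 (adjusted p = 0.023), which was -0.25 and not called after upper-quartile scaling, and -0.68 and not called without day 22. Among DNA replication genes 14 of 24 fell and 1 rose (fry, adjusted p = 0.0024, 0.2 after upper-quartile scaling, with a range of 0.00063 to 0.66 over the alternatives; adjusted p = 0.75 with an estimated correlation), the origin gene ORC1 with a trend of -1.94 ± 0.25. In the cell cycle exit list 7 of 14 rose (8, with 2 falling, adjusted over the list alone; fry, adjusted p = 0.0032; adjusted p = 0.35 with an estimated correlation). GAS1, a growth arrest protein, rose by 3.24 ± 0.32, and CCND2, a G1 cyclin, was at 45 FPKM on day 0 and 62.1 on day 20.

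Glycolysis genes fell in 16 of 24 cases and none rose (the same count adjusted over the list alone; fry, adjusted p = 0.00011; adjusted p = 0.48 with an estimated correlation), with a median of -1.46, or -0.85 after upper-quartile scaling. LDHA, a lactate dehydrogenase, fell by 3.73 ± 0.32, and the glucose transporter gene SLC2A3 fell by 4.19 ± 0.78, from 320.1 FPKM on day 0 to 105 on day 16 and 7.5 on day 18. Genes of oxidative phosphorylation fell in 8 of 25 cases (6 adjusted over the list alone; fry, adjusted p = 0.035, 0.59 after upper-quartile scaling, with a range of 0.00051 to 0.95 over the alternatives; adjusted p = 0.82 with an estimated correlation). Their list lost its call without day 0, 2, 4, 8, 10, 12, 14, 16 or 20. A similar share of all tested genes fell (4416 of 13701). Against other genes the oxidative phosphorylation list was not called (camera with a preset correlation, adjusted p = 0.18). In the hypoxia list 6 of 18 fell and 2 rose (adjusted p = 0.15), the vasodilator peptide gene ADM with a trend of -4.26 ± 0.70. Unfolded protein and heat stress genes fell in 7 of 19 (5 adjusted over the list alone; fry, adjusted p = 0.027, 0.29 after upper-quartile scaling and 0.094 without day 0, with a range of 0.02 to 0.72 over the alternatives; adjusted p = 0.82 with an estimated correlation), and HSPA5, an ER chaperone, fell by 2.0 ± 0.34, or by 1.06 after quantile normalization. Their median of -0.58 was 0.03 after upper-quartile scaling. The call of this list was lost also without day 18 or 20.

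Housekeeping genes fell in 12 of 25 cases (fry, adjusted p = 0.00079, 0.074 after upper-quartile scaling, with a range of 0.00013 to 0.074 over the alternatives; adjusted p = 0.5 with an estimated correlation). ACTB fell by 1.82 ± 0.34, or by 1.21 after upper-quartile scaling, and its trend was -0.87 and not called after quantile normalization. Ribosomal protein genes fell in 2 of 26 (adjusted p = 0.37) and had median deviations of 1.33, 1.22, 0.75 and 0.21 log2 units on days 8, 10, 18 and 22, 0.35 on day 0 and 0.01 or lower on the other days. The ribosomal protein list was called as falling with an indicator for these libraries or without them (medians of -1.5 and -1.36, against -0.57 as deposited and 0.04 after upper-quartile scaling). The 17 histone genes, none of which was called, moved with days 8, 10 and 18, HIST1H4H standing at 2.33, 56.8, 44.8 and 23.7 FPKM on days 6, 8, 10 and 18. The mitochondrially encoded genes of a list set up to judge RNA quality are not in the table.

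Among chromatin genes, 7 of 18 DNA methylation and Polycomb genes fell and 4 rose (median -0.14, 0.34 after upper-quartile scaling; adjusted p = 0.06, 0.00068 without day 0, with a range of 0.00068 to 0.93 over the alternatives). The Polycomb genes PHC1 and CBX8 had trends of -3.72 ± 0.59 and 2.88 ± 0.43. In the list of BAF chromatin remodelling subunits 4 of 16 rose and 4 fell (adjusted p = 0.73, 0.037 after upper-quartile scaling, with a range of 0.026 to 0.91 over the alternatives; median -0.49, mean 0.09), SMARCD3 with a trend of 3.62 ± 0.41. In the p53 list 2 of 20 rose and 1 fell (1 and 0 adjusted over the list alone; adjusted p = 0.81; median -0.02, mean 0.12). Immediate early genes rose in 6 of 16 and fell in 4 (6 and 5 adjusted over the list alone; adjusted p = 0.39, 0.037 after upper-quartile scaling, with a range of 0.037 to 0.91 over the alternatives), EGR1 with a trend of 3.68 ± 0.67 and KLF6 with -2.26 ± 0.50. In the cholesterol list 3 of 20 fell and 1 rose (2 and 0 adjusted over the list alone; adjusted p = 0.096, and called without day 20, with a range of 0.014 to 0.91 over the alternatives). Matrix and mesenchyme genes rose in 3 of 19 and fell in 2 (2 and 2 adjusted over the list alone; adjusted p = 0.81), COL3A1 with a trend of 5.19 ± 1.29 and THY1 with -2.84 ± 0.43. Where no second count is given, the count adjusted over the list alone was the same. Across the 43 lists tested, 10 rose and 13 fell, against 18 and 6 after upper-quartile scaling and 17 rising without day 22. Of the 23, 16 were also called against other genes with a preset correlation of 0.01, and 2, Notch with proneural factors and forebrain patterning, with an estimated correlation. Those not called with the preset correlation were all falls (camera, adjusted p of 0.18 to 0.94). They were the neural crest, glia, oxidative phosphorylation, unfolded protein, endoderm, FGF and retinoic acid lists. For the last 3 camera gave the direction as up. These falls were not shown to exceed that of other genes.

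**Figure D3:**
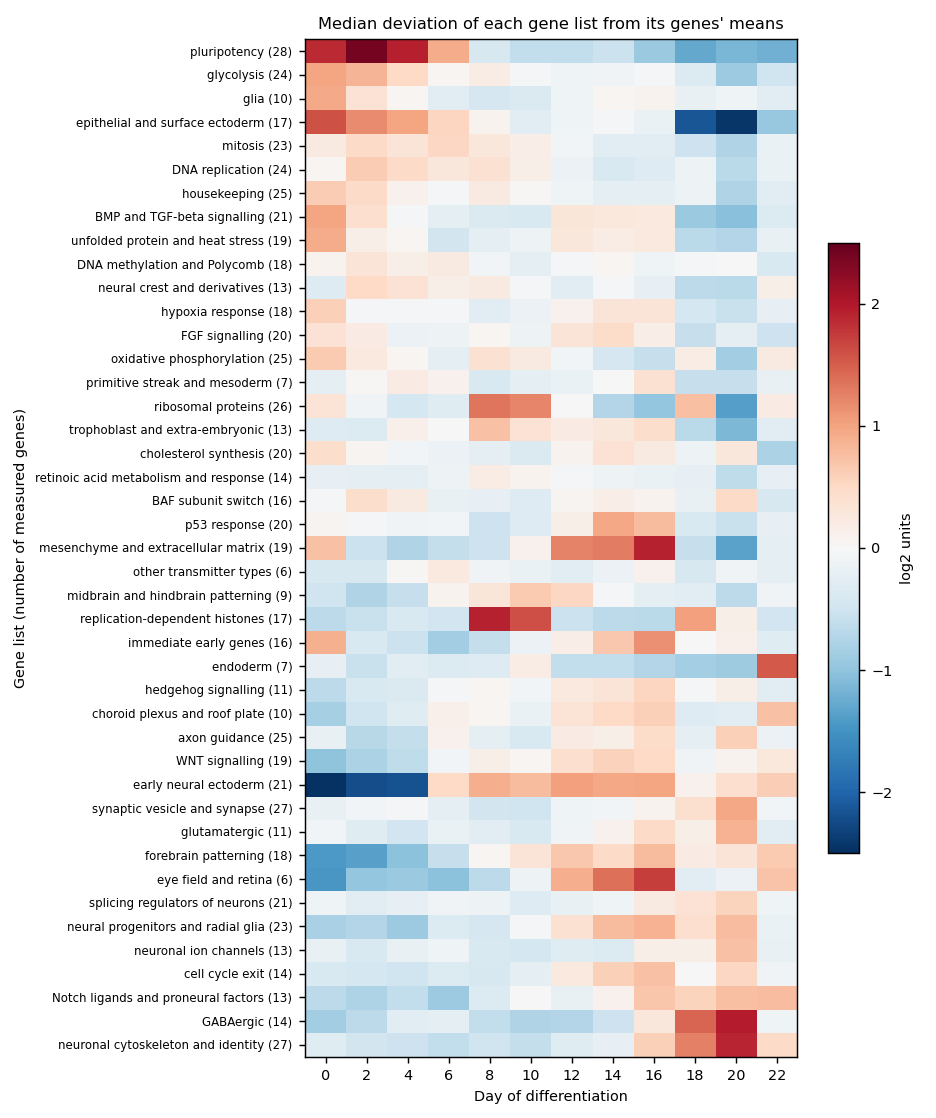
Median over each list's genes of the deviation from the gene's mean (log2 units, colour), for 43 lists in rows and the 12 days in columns, with the number of measured genes in parentheses. Pluripotency and epithelial lists are highest on days 0 to 4, neuronal and GABAergic lists on day 20, and the endoderm list on day 22.

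The largest fitted rises between the ends of the course belonged to DLK1, FABP7 and LHX2, described above, and to SMOC1, EMX2, LIX1 and TMSB15A. SMOC1, a matrix protein that antagonizes BMP, rose by 4.75 ± 0.68 (adjusted p = 0.00029), from 0.965 FPKM on day 4 to 40.2 on day 8. LIX1 rose by 3.82 ± 0.73 (adjusted p = 0.0016) with 37.3 FPKM on day 6. TMSB15A rose by 3.98 ± 0.91, with 169, 203, 174 and 189 FPKM on days 8, 10, 18 and 22 and 39.6 on day 20, thus moving with the libraries high in short transcripts. The small nucleolar RNAs SNORA2A and SNORD10 were also among the 10 largest. The largest falls were in ACTA1, BCYRN1, ESRG, ACTC1, CER1, TDGF1, POU5F1, CAV1, PODXL and GRPR. ESRG, a non-coding transcript of pluripotent cells, fell by 9.33 ± 0.88 (adjusted p = 3.2e-05), and PODXL, a surface sialomucin, fell by 6.46 ± 0.83. ACTA1, a muscle actin, was at 453 FPKM on day 0 and 13 on day 2 (trend -5.51 ± 0.70, -3.25 without day 0). The calls for CAV1 and ACTC1 were lost without day 0 (trends of -1.02 and -2.83, against -3.33 ± 0.89 and -3.89 ± 1.34), for ACTC1 also without day 20 (-3.05) and after upper-quartile scaling. The calls for BCYRN1 (without day 22, -3.05), SNORA2A (without day 2, 4 or 22, 4.62 to 4.89) and SNORD10 (without day 2, 4.29) were lost as well.

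A further comparison took up genes whose fitted level was highest or lowest inside the course. A peak was found for 306 genes and a trough for 125, with 159 of the fitted peaks on day 16 and 51 of the fitted troughs on day 6. The form of a cubic curve limits where it can turn, so these counts do not show on which day expression was highest or lowest. COL2A1, a fibrillar collagen, went from 2.33 FPKM on day 6 to 304 on day 14 and 48.6 on day 22 (limma F test, adjusted p = 0.00024). EPAS1, a hypoxia-inducible factor, was at 31.6 FPKM on day 16 and 1.2 on day 18 (adjusted p = 0.015), and TGM2, a protein cross-linking enzyme, at 60.8 and 0.193 (adjusted p = 0.032). The smooth muscle actin gene ACTA2 was at 1.74 FPKM on day 6, 42.8 on day 12 and 1.58 on day 20 (adjusted p = 0.022). CLSTN2 and MPPED1 reached 41.5 FPKM on day 16 and 54.1 on day 14. HESX1 and PAMR1 peaked earlier, with 57.3 FPKM on day 6 and 113 on day 8. DLK1 and GABRP were also among the 10 highest peaks.

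The deepest troughs were in DLL3, DNER, CREB5, WNT7A and INA. DNER, a neuronal Notch ligand, was at 7.34 FPKM on day 0, 0.345 on day 2 and 33.7 on day 20 (adjusted p = 0.0005). INA, a neurofilament subunit, was at 3.12, 22.5 and 47 FPKM on days 8, 18 and 20 (adjusted p = 0.0017), and WNT7A, listed at 0 on days 4 and 6, was at 5.46 and 10.8 FPKM on days 0 and 20. The number of troughs was 236 without day 22 and 243 without days 8, 10, 18 and 22. With a pseudocount of 0.1 there were 505 peaks and 352 troughs, and with a quadratic curve 103 and 48.

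Single pairs of days were compared by the median log2 difference of each list, with its percentile among 10000 random lists of the same size and expression; these describe 2 libraries and carry no p-value. From day 0 to day 6 the early neural ectoderm list was higher by 2.9 (percentile 100; 15 of 21 genes higher by at least 1). The pluripotency list differed by -0.93 (percentile 0), immediate early genes by -1.71, unfolded protein and heat stress genes by -1.37 and matrix genes by -1.24 (all at percentile 0). From day 6 to day 14 the pluripotency list differed by a further -1.05 (percentile 0), while progenitor genes were higher by 1.13 and eye field genes by 2.35 (both at percentile 100). Matrix genes were higher by 2.39 and immediate early genes by 1.82, again at percentile 100, with 14 of 19 and 13 of 16 members higher by at least 1. COL3A1 went from 0.356 to 47.5 FPKM between these days, and the p53 list was higher by 0.94 (percentile 100), its member CDKN1A, a cell cycle inhibitor, going from 4.45 to 70.8 FPKM.

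From day 14 to day 22 matrix genes differed by -1.26, p53 genes by -1.26 and cholesterol synthesis genes by -1.26 (all at percentile 0). Neuronal identity genes were higher by 0.57 and GABAergic genes by 0.48 (both at percentile 100), while the progenitor list differed by -0.76 (percentile 1.4) and the glutamatergic list by -0.47 (percentile 3.9). Genes of oxidative phosphorylation were higher by 0.65 and ribosomal protein genes by 0.93 (both at percentile 100); day 22 is high in short transcripts, and ribosomal protein mRNAs are short. Over the whole span from day 0 to day 22 the early neural ectoderm list was higher by 3.44, forebrain genes by 2.78 and Notch and proneural genes by 1.79 (all at percentile 100), the progenitor list differed by -0.02 (percentile 99.6), and the pluripotency and epithelial lists differed by -2.66 and -2.71 (both at percentile 0). Of 43 lists, 10 lay above the highest 2.5% and 12 below the lowest 2.5% of random lists from day 0 to day 6, 16 and 4 from day 6 to day 14, and 10 and 11 from day 14 to day 22.

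Steps between neighbouring days were compared to see where along the course expression moved most. From day 6 to day 8, FABP7 went from 4.23 to 88.8 FPKM and PRDM14 from 29.8 to 3.12. From day 16 to day 18, the collagen genes COL1A1 and COL1A2 went from 177 and 145 to 2.69 and 2.44 FPKM. The genes with the 3 largest differences per step, as the rule set before the data were examined asked, were mostly small nucleolar and Cajal body RNAs such as SNORA63, SNORD97 and SCARNA22, which were listed at 0 in several libraries each; FABP7 and PRDM14 were picked for this step, and the genes of the next paragraph other than CLSTN2, NOS2 and AFP, after their values were seen. Differences of at least 1 log2 unit were found for 2700 of 13701 genes (19.7%) from day 6 to day 8, 2570 from day 16 to day 18 and 2337 from day 20 to day 22. There were 1497 such genes from day 0 to day 2, 1408 from day 18 to day 20 and 1117 from day 10 to day 12. The other 5 steps had 98 to 657. The 3 steps with the most genes and that from day 10 to day 12 join a library high in short transcripts to one that is not, as does the step from day 18 to day 20. With an indicator for the 4 libraries subtracted, a choice made after seeing the data, the counts were 578, 765 and 1194 for the 3 steps, 147 from day 10 to day 12, 289 from day 18 to day 20 and 1497 from day 0 to day 2. With each library's trend with transcript length removed they were 2359, 2303 and 2011.

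Lower values made up 63.2% of the genes that differed from day 16 to day 18, 42.9% after upper-quartile scaling, 77.7% from day 18 to day 20, 63.6% after quantile normalization, and 58.2% from day 2 to day 4, 37.6% after upper-quartile scaling. At the first step the metallothionein genes MT1G and MT2A went from 125 and 149 FPKM to 0.729 and 1.31, and LHX5 from 0.104 to 10.9. From day 4 to day 6 RAX, an eye field factor, went from 0.766 to 23.5 FPKM, and NANOG from 19 to 1.41. From day 10 to day 12 CLSTN2 went from 1.69 to 19.3 FPKM, NOS2 from 2.98 to 25.5, EMX2 from 1.63 to 14.8 and SLIT2 from 1.84 to 15.9. From day 14 to day 16 the interneuron genes DLX2 and DLX6-AS1 went from 0.639 and 0.999 FPKM to 4.8 and 14.8, and EGR1 from 9.62 to 65.6. From day 20 to day 22 DLX6-AS1 went from 61.2 to 6.06 FPKM, the cortical factor POU3F3 from 94.4 to 7.12, and AFP from a listed 0 to 68.7.

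**Figure D4:**
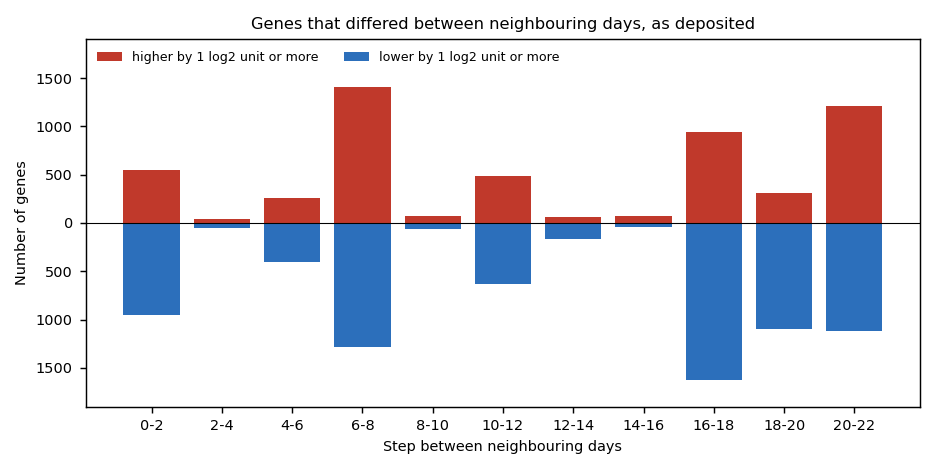
Number of genes higher (red, upward) or lower (blue, downward) by at least 1 log2 unit in the later library of each pair of neighbouring days, in the values as deposited. The tallest bars are for day 6 to 8 (1412 up, 1288 down), day 16 to 18 (945 up, 1625 down) and day 20 to 22 (1214 up, 1123 down).

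The order of the libraries was described by splitting the course into contiguous segments that hold the most variance. The split into 2 segments fell between days 6 and 8 (41.9% of the sum of squares), when POU5F1 went from 142 to 32.8 FPKM. The split into 3 added a boundary between days 10 and 12 (55.6%), where EMX2 stood at 1.63 and 14.8 FPKM. The split into 4 added days 16 and 18 (69.1%), where the matrix gene FN1, chosen after its values were seen, stood at 889 and 23.5 FPKM, and the split into 5 added days 0 and 2 (79.4%). All these boundaries were found in 100% of 1000 bootstraps of the genes, which resample genes and not cultures. The split into 6 added days 20 and 22 in 94.7% of bootstraps. The boundaries between days 6 and 8, 10 and 12, and 16 and 18 each separate libraries that differ in short transcripts. They were kept with the length trend removed, whereas with the indicator for the 4 libraries subtracted the boundary between days 10 and 12 was absent from every split into 2 to 6 segments and the one between days 0 and 2 came with 4.

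By rank correlation over all tested genes, the library of day 22 was closest to that of day 10 (0.939), against 0.865 with day 20, and the library of day 18 was closest to that of day 22 (0.935). The most alike pair was days 2 and 4 (0.985). The first principal component held 46.7% of the variance and placed day 0 at -83.7 and day 18 at 61.7. The second held 20.5% and placed days 8 and 10 at 61.1 and 47.3, days 18 and 22 at 24.3 and 21.9, and days 14, 16 and 20 at -42.1, -49 and -44.7.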

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

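Tests with an indicator for days 8, 10, 18 and 22, without these days, without small RNA rows and with the length trend removed were chosen after seeing the data; the others were planned. None of the results given was called in the other direction under any setting, and the cause of the changes below was not tested except where a setting uses fewer genes or libraries.

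Smaller pseudocounts gave more transient genes: 505 peaks and 352 troughs at 0.1, and 564 and 405 at 0.01, against 306 and 125. The filter of 5 FPKM, which tests fewer genes, gave 1036 rises, 601 of them by at least 1 log2 unit. Upper-quartile scaling gave 3037 rises and 2304 falls, 1868 and 1330 by at least 1 log2 unit, with 18 lists rising and 6 falling, against 10 and 13. Quantile normalization gave 2474 falls, 1425 rises and 1443 falls by at least 1 log2 unit, and 8 lists falling. A quadratic curve gave 103 peaks and 48 troughs. A natural spline has no linear term and so gave no rises or falls, and a straight line gave no test of variation, peaks or troughs. The indicator gave 8360 varying genes. Leaving out days 8, 10, 18 and 22 gave 8859 varying genes, 2846 rises, 1458 by at least 1 log2 unit, 243 troughs and 16 lists rising. The step with the most genes began on day 6, on day 20 after quantile normalization, on day 16 for differences of at least 2 log2 units, and on day 0 with the indicator.

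Leaving out 1 day at a time gave 4007 to 6032 varying genes, 1423 to 2139 rises, 3444 to 4600 falls, 791 to 1302 rises and 2488 to 3139 falls by at least 1 log2 unit, 248 to 376 peaks and 94 to 236 troughs, with 8 to 17 lists rising and 9 to 13 falling. The highest numbers of troughs (236) and rising lists (17) came without day 22.

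Of 333 named genes, 232 were called and 167 of these kept the call under all settings. Upper-quartile scaling ended 15 calls and added 5, leaving out day 0 ended 22, and leaving out day 22 ended 11 and added 22. Of the 23 lists called, 11 kept the call throughout. Upper-quartile scaling ended 7 and added 8, leaving out day 0 ended 7, and leaving out day 22 ended 1 and added 8. Depth is unknown, so what it limits could not be judged.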

Other observations

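The tests of short transcripts, of a second library of another day under the day 22 label, of mesenchymal cells and of other orders of the libraries were chosen after the results were seen. The labels give no factor besides the day, so no biological explanation was tested by the design.

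In 100 orders of the 12 libraries, 1, the real one, gave as many varying genes (5544, against at most 1227 in the others). Again 1, the real one, gave as many rising or falling genes (6171 against 629). Any gradual change along the days, or likeness of neighbouring libraries, would also set the real order apart. Chance differences between single libraries are therefore not excluded.

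The excess of short transcripts on days 8, 10, 18 and 22 was not limited to ribosomal protein genes, as without them and small RNAs the correlation with length was -0.22 or lower in all 4 libraries. Histone genes, whose mRNAs lack a poly(A) tail, lay at least 1.2 log2 units above all genes on days 8, 10 and 18. Weaker selection of polyadenylated RNA is a candidate explanation there. However, histone transcripts are short too, and the list was not compared with other genes of like length, so the value does not decide it. On day 22 the histone genes lay at -0.26, without an excess of the size seen on those days. The remaining libraries lay at -0.83 to -0.46, apart from day 20 at 0.37. The deviations are taken from means that include days 8, 10 and 18, so 0 is no baseline. The value therefore does not decide the question for day 22. What set day 22 apart stays open.

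Neuronal genes were lower on day 22 than on day 20, with a median of -1.51 and 16 of 27 lower by at least 1 log2 unit, DCX going from 148 to 13.9 FPKM and GAD1 from 17.3 to 2.12. With the length trend removed the median was -1.45, so the trend with transcript length does not account for it. That removal left 2011 genes differing by at least 1 log2 unit at this step, against 2337 as deposited. With the indicator for days 8, 10, 18 and 22 subtracted there were 1194. Other differences shared by these libraries are therefore not excluded as a part of it. On day 18, also 1 of the 4, the median deviation of the neuronal list was 1.26. It was 0.59 on day 16, 1.9 on day 20 and 0.48 on day 22. On days 8 and 10 it was -0.5 and -0.59, against -0.61 on day 6 and -0.31 on day 12. For this list, these values argue against a difference shared by all 4 libraries as the whole account. Fewer neurons among progenitors of the same culture would leave progenitor genes level or higher. These had a median of -0.82 as deposited and -0.60 with the length trend removed. Endoderm, epithelial and forebrain genes had 1.39, 1.23 and 0.70 as deposited, and 1.34, 1.49 and 0.5 with the length trend removed. The day 22 library differed by at least 1 log2 unit in 711 or more genes from each other day (138 between days 8 and 10). No day has a second library, so how far 2 libraries of the same day would differ is unknown and this count does not decide. AFP stood at 68.7 FPKM against at most 1.93 on the other days, APOA1 at 27.9 against 2.37 and APOA2 at 28.6 against 1.3. These values argue against a second library of another sampled day of the same culture. Swapped labels, an unsampled day, another culture and another mix of cells were not tested and stay open.

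Matrix genes were higher on day 14 than on day 6 by a median of 2.39, and differed from day 16 to day 20 by -3.44. With the length trend removed the first median was 2.3, which argues against transcript length. The 14 of 19 members higher by at least 1 log2 unit, COL1A1 at 81.9 and COL3A1 at 47.5 FPKM on day 14 among them, are the pattern itself and do not decide whether mesenchymal cells were present. On day 0, when the matrix list was also higher than on day 2, COL3A1, LUM and DCN lay at 0.04 FPKM or less, which argues against such cells then. A list of 15 YAP and TEAD target genes not looked at before had a median of 1.93 from day 6 to day 14 (percentile 100), -1.25 from day 0 to day 2 and -2.04 from day 16 to day 20, so a shared response of these genes may be involved, which the list cannot tell from a change in cell types.

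Families named by symbol, 121 in all and grouped after their values were seen, were compared with other genes by camera, and 6 passed with a preset correlation and none with an estimated one. Of these, SOX (8 rose and 3 fell of 15, adjusted p = 0.0066), DDX (1 and 23 of 34, adjusted p = 0.037) and PSMD (none and 10 of 14, adjusted p = 0.037) did not pass after upper-quartile scaling (adjusted p = 0.053, 0.11 and 0.084). Of 13 genes for intraflagellar transport, which builds cilia, 5 rose and none fell (median 0.60, camera with a preset correlation, adjusted p = 0.0014; adjusted p = 0.84 with an estimated correlation), IFT81 with a trend of 2.07 ± 0.24 and IFT140 with 1.61 ± 0.20; 9 rose after upper-quartile scaling, with a median of 1.13. Of 19 nucleoporin genes 16 fell (median -1.37, adjusted p = 0.0022; adjusted p = 0.97 with an estimated correlation), NUP50 with a trend of -1.77 ± 0.32; 12 fell after upper-quartile scaling, with a median of -0.78. Of 51 genes for translation initiation factors 31 fell (median -1.04, adjusted p = 0.0009; adjusted p = 0.97 with an estimated correlation), EIF5A with a trend of -2.42 ± 0.38; 16 fell and 1 rose after upper-quartile scaling, with a median of -0.44.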
